A study of Homo sapiens with 4 samples.

How the data were processed

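Total RNA of tamoxifen-resistant MCF-7 cells was measured on 4 one-colour Agilent expression arrays. MCF-7 is an established estrogen receptor-positive breast adenocarcinoma cell line, and per the labels the derivative used here no longer responds to tamoxifen, an estrogen receptor antagonist used against such tumours. Per the labels, 2 arrays held RNA of cells infected with lentivirus carrying a control clone and 2 held RNA of cells infected with lentivirus carrying the open reading frame of human ELOVL2, an enzyme that elongates polyunsaturated fatty acids. Per the labels' protocols, RNA was purified with a Zymo Research column kit and converted to Cy3-labelled cRNA with Agilent's Quick Amp kit. Nothing in the labels says whether the arrays of a group came from separate infections or cultures. No p-value below is therefore known to cover the spread between infections or cultures. The tests of single genes rest on the spread between these arrays, which may be technical. The list tests by camera compare a list's genes with the other genes on the same arrays.

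The deposited table holds 1 linear Cy3 intensity per probe and array. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 11.0.1.1. The background correction, the flags for dim or saturated spots and any filter on probes are not given in the sources used here. The table has 58201 probes with no missing value. The deposited intensities were not brought to a common scale between arrays, since their 75th percentiles were 72.3 and 78.6 on the control arrays and 96.8 and 77.4 on the ELOVL2 arrays. Between 45.7% and 48.7% of the probes on each array lay within 2 times that array's lowest intensity, which was 1.89 and 2.27 on the control arrays and 2.30 and 2.53 on the ELOVL2 arrays. Probes this dim are called near the lowest signal below, because no detection flags were used, and the highest of these 4 limits after scaling served as a common floor. Where both arrays of 1 group lay under it, only a lower bound of the fold is given, which sets the brighter group's mean against the floor. No bound is given where an array of the brighter group lay under that floor. The number of arrays limits the precision.

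A probe's gene was taken from the platform annotation and updated through its RefSeq accession. A single gene was listed for 36812 probes, none had several, and 21389 had no gene in that table. The symbol was set by the accession for 32274 probes, was already current for 4310, was updated as a synonym for 223 and was kept as the array gave it for 5. This gave 24705 genes, each read from its brightest probe over all 4 arrays. The build behind the array design is not given in the sources used here, so no genome coordinates are printed. Where paralogs are nearly identical, as for SAA1 and SAA2, the AKR1C genes, the metallothioneins or HLA genes, a probe can bind several of them, and such genes are uncertain as single genes.

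The plan fixed before the data were examined assumed that values could be tested as deposited after taking log2. Because the deposited values turned out to be unscaled intensities, each array's 75th percentile of the log2 intensity was subtracted first, and the fit without scaling is given as an alternative. A level is therefore a log2 intensity relative to that percentile. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 24705 genes and a threshold of 0.05. The fit has 2 residual degrees of freedom per gene. limma estimated infinite prior degrees of freedom, so each gene's own spread was replaced by that of genes of its level, and 3.56% of the genes had a spread beyond that model's 99th percentile. Very small p-values therefore say little about a single gene, and the size of a change and its range over arrays carry more. Each SE given below also comes from that shared spread and is not the gene's own. Data were simulated with these levels and spreads over 24705 genes. All changed genes lay above the median level, so recovery among dimmer genes was not tested. The fit recovered 28 of 50 genes changed 1.5-fold, 46 of 50 changed 2-fold, and 50 of 50 at 4-fold and at 8-fold, with 8 false calls. It called 0 genes where nothing was changed. The simulated spread depended on level alone and so does not include genes with a larger spread of their own.

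Before the data were examined, 24 gene lists were fixed from textbook knowledge, among them markers of stromal and immune cells and ribosomal protein genes as technical controls. Each list was compared with the other genes by camera with a preset correlation of 0.01 between genes, with adjustment over the 24 lists. On simulated data camera called the single list shifted by 0.5 on the log2 scale and 0 of the others. The simulated genes varied independently and all lay above the median level, so this does not test the preset correlation. camera with an estimated correlation rests on 2 degrees of freedom here, and fry tests whether a list's genes moved one way without comparing them with other genes. The genes named in the text follow a rule fixed at the same time. They are ELOVL2, AKT1, AKT2, AKT3, THEM4 and ESR1, the 6 largest rises and 6 largest falls past the threshold among genes above the median level, 2 members of each list that camera called and 1 member of every other list. List members were taken by the largest absolute change past the threshold, filled by the smallest p. No probe was named AKT3 here. Any other gene named in the text was chosen after its values were seen.

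The alternatives planned were fits without the trend or with a robust prior, quantile normalization, centring on the median, leaving out the dimmest 25% or 50% of the genes, averaging a gene's probes, adding 16 to each intensity, a 1.5-fold minimum, an unadjusted threshold, the replicate number as a block, leaving out each array in turn, and the other list tests. A fit without scaling, a floor of 2 times the lowest signal and a test of every probe were added after the data were seen. Bootstrap intervals in the closing section used 2000 resamples of the genes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9.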

Results

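The study asked what ELOVL2 does to gene expression in breast cancer cells that have become resistant to tamoxifen, with the AKT pathway named in its title. Expression was measured on 2 arrays of control-infected cells and 2 arrays of cells infected with the ELOVL2 reading frame. The arrays of a group resembled each other closely. Among genes above the median level, the SD of the log2 difference was 0.195 between the control arrays and 0.194 between the ELOVL2 arrays, against 0.613 to 0.677 between arrays of different groups.

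ELOVL2 itself, read by 1 probe, was higher in the cells that received its reading frame. Its intensity was 2195 and 2624 on the control arrays and 4952 and 4112 on the ELOVL2 arrays. The log2 difference was 0.71 ± 0.09 (SE, n = 2 arrays per group), a 1.64-fold rise (limma, adjusted p = 1.2e-14). Without the intensity trend the adjusted p was 0.0508. The probe's place in the transcript is not given in the sources used here, so it is not known whether it reads the introduced reading frame, the endogenous gene or both.

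Between the groups, 3155 genes rose and 5229 fell with ELOVL2 (limma, adjusted p under 0.05, 24705 genes), and of these 1870 and 2794 changed at least 1.5-fold. The largest falls among genes above the median level were in MGP, which encodes an inhibitor of tissue calcification, 50.1-fold lower, and in DHRS2, a short-chain dehydrogenase, 36.9-fold lower. KLHDC7B fell 27.7-fold, the secreted protease inhibitor SLPI 26.4-fold, S100A7 (psoriasin) 25.1-fold and the signalling adaptor SHC4 19.3-fold. DHRS2 had intensities of 20397 and 21553 on the control arrays and 751 and 567 on the ELOVL2 arrays. The largest rises were in LGI4 (19.6-fold), LMO7DN (12.1-fold), CAV1, the main protein of caveolae (log2 difference 3.58 ± 0.15, SE), the myelin protein gene PMP22 (10.4-fold), GOLGA7B (10.3-fold) and LETR1 (10.0-fold). These folds are those of each gene's brightest probe as scaled. With a gene's probes averaged, KLHDC7B fell 9.84-fold, and PMP22 rose 5.35-fold, GOLGA7B 3.64-fold, LMO7DN 3.57-fold and LETR1 3.22-fold. Adding 16 to each intensity, which shrinks changes that reach low signals, gave falls of 11.5-fold for S100A7, 9.06-fold for SLPI and 7.10-fold for SHC4, and rises of 7.28-fold for LGI4 and 5.06-fold for GOLGA7B.

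PMP22 was alike on the arrays of each group. CAV1 had intensities of 35.5 and 25.9 on the control arrays, and its rise ranged from 9.82-fold to 14.6-fold with single arrays left out. Another 4 of the large rises were more uneven between the control arrays. LMO7DN had intensities of 15.5 and 86.6 there, LGI4 of 4.15 and 19.7, GOLGA7B of 7.43 and 24.3 and LETR1 of 65.0 and 195. Leaving out control replicate 1 lowered the rise of LGI4 to 9.36-fold, of LMO7DN to 5.34-fold, of GOLGA7B to 5.92-fold and of LETR1 to 6.01-fold, and leaving out control replicate 2 raised them to 40.9-fold, 27.4-fold, 17.8-fold and 16.6-fold. LGI4 and LMO7DN did not pass without the trend, with adjusted p of 0.0512 and 0.0809, and the other 10 of these 12 genes did. With a robust prior LGI4, LMO7DN and LETR1 did not pass (adjusted p = 0.145, 0.221 and 0.122), and under quantile normalization neither LGI4, LMO7DN nor GOLGA7B did (adjusted p = 0.0639, 0.0985 and 0.0583).

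The direction split depended on how the arrays were scaled. Of the genes called, 37.6% were higher with the 75th percentile, 48.0% with quantile normalization (2144 higher and 2327 lower), 26.8% with centring on the median (2325 and 6340) and 64.1% with no scaling (2393 and 1340). Without scaling the median gene lay at a log2 difference of 0.22 and with median centring at -0.095, against 0.02 here. Without the trend 882 genes rose and 1573 fell.

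**Figure D1:**
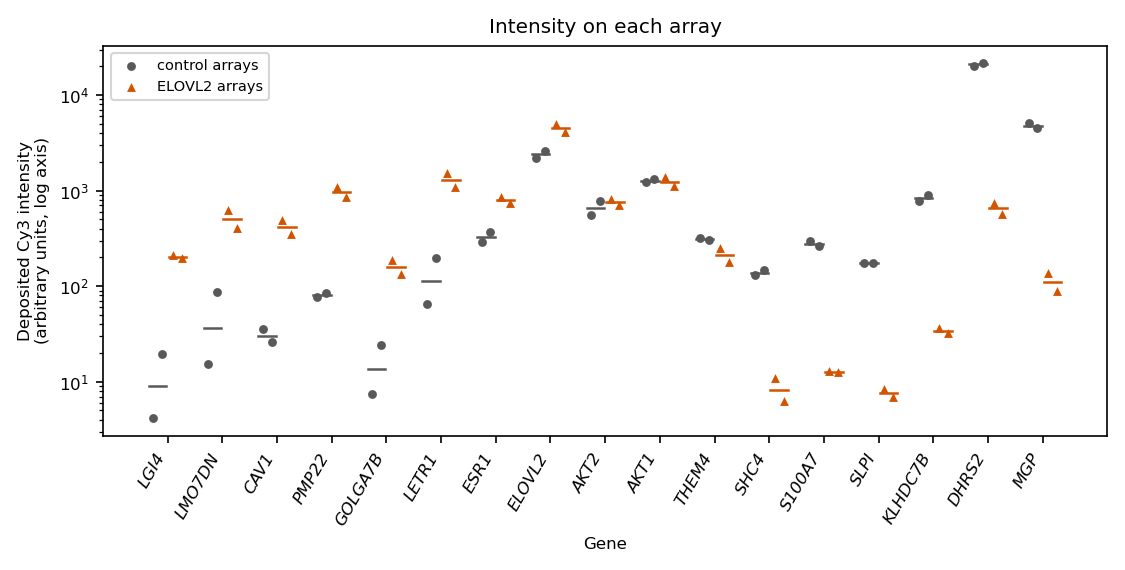
Deposited Cy3 intensity (arbitrary units, log axis) of ELOVL2, ESR1, THEM4, AKT1, AKT2 and the 12 genes of largest change, with 1 point per array and a line at each group's geometric mean. The control points of LMO7DN lie at 15.5 and 86.6, and those of MGP at 5083 and 4538 against 137 and 88.3 with ELOVL2.

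Genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, were lower as a group. Of 29 measured members 24 fell, 1 rose and 4 did not pass, with a median log2 difference of -1.34. Adjusted over the list alone, 25 fell and 3 rose. CRELD2, a secreted stress-induced protein, fell 6.42-fold and the chaperone cofactor SDF2L1 5.44-fold. The chaperone HSPA5 had a log2 difference of -1.59 ± 0.09 (SE) and the stress transcription factor gene DDIT3 of -2.23. PSAT1, an enzyme of serine synthesis, was the member that rose, with a log2 difference of 2.08. XBP1 (0.35) and ATF4 (-0.35) did not pass. The list was lower than other genes (camera, adjusted p = 4.8e-38, or adjusted p = 0.1 with an estimated correlation). Quantile normalization left 21 falls and 1 rise, and the fit without the trend 19 falls.

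Interferon-stimulated genes were lower as a group. Of 46 measured members 40 fell, none rose and 6 did not pass, with a median log2 difference of -1.13. Adjusted over the list alone, 40 fell and 1 rose. MX1, a dynamin-like antiviral GTPase, fell 5.98-fold and IFIT3, which binds viral RNA complexes, 5.59-fold. The antigen presentation genes HLA-B (-1.46), HLA-C (-1.41) and PSMB9 (-1.86, an immunoproteasome subunit) fell as well on the log2 scale, while CXCL10 (0.53) and STAT2 (0.19) did not pass. The list was lower than other genes (camera, adjusted p = 6.0e-37, or adjusted p = 0.1 with an estimated correlation). Among NF-kB and inflammatory genes 14 of 28 fell, 2 rose and 12 did not pass, and 16 fell and 2 rose adjusted over the list alone. The acute-phase genes SAA2 and SAA1 fell 14.6-fold and 7.21-fold, though a probe can read both. The fall of SAA2 was 5.49-fold with its probes averaged and 5.83-fold with 16 added, and that of SAA1 4.77-fold with 16 added. NFKB1 and NFKBIA were the members that rose, with log2 differences of 0.73 and 0.32. The camera adjusted p of this list was 0.00018, or adjusted p = 0.16 with an estimated correlation. The fits without the trend left 31 interferon-stimulated and 10 inflammatory genes that fell.

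Genes of fatty acid synthesis and elongation were lower. Of 18 measured synthesis genes 14 fell, none rose and 4 did not pass, with 15 falls adjusted over the list alone and a median log2 difference of -0.61. ACACB, an acetyl-CoA carboxylase, fell 3.44-fold and PNPLA3, a lipid droplet hydrolase, 2.30-fold. FASN (fatty acid synthase) had a log2 difference of -0.77 and ACLY (ATP citrate lyase) of -0.86. ACACB did not pass without the trend (adjusted p = 0.0749), under quantile normalization (adjusted p = 0.1) or with its probes averaged (1.86-fold, adjusted p = 0.0857), it fell 2.27-fold with 16 added, and PNPLA3 did not pass without scaling (adjusted p = 0.0513). Of 25 elongation and desaturation genes other than ELOVL2, 13 fell, 6 rose and 6 did not pass, and the numbers were unchanged when adjusted over the list alone. FADS1, the delta-5 desaturase of polyunsaturated fatty acids, fell 2.78-fold, or 1.66-fold with its probes averaged, and the elongase ELOVL5 had a log2 difference of -1.45. ACSL6 passed (adjusted p = 0.0032), but it was near the lowest signal on 3 of 4 arrays, with intensities of 2.14 and 2.59 on the control and 2.92 and 20.5 on the ELOVL2 arrays, so the call rests on 1 array and no fold is given. The log2 difference was -0.048 without ELOVL2 replicate 2. The call was lost without the trend (adjusted p = 0.492), under quantile normalization (0.495), without the dimmest 25% of the genes (0.167), with averaged probes (0.143), with 16 added (0.189) and with a floor on low signals (0.276). The camera adjusted p was 5.1e-05 for fatty acid synthesis and 0.0020 for elongation, or adjusted p = 0.26 and adjusted p = 0.21 with an estimated correlation. Without the trend 7 and 9 genes of these lists fell, and elongation did not pass with a floor on low signals (adjusted p = 0.0552).

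The lists of cholesterol synthesis and of fatty acid oxidation did not pass camera (adjusted p = 0.0785 and 0.11), or with an estimated correlation (adjusted p = 0.35 for both). The cholesterol list did pass as lower in 5 of 14 other settings, with adjusted p of 0.0185 without the trend, 0.035 with median centring, 0.0483 without the dimmest 25%, 0.0363 with averaged probes and 0.0401 with the floor. In the first, 13 of 22 members fell, 1 rose and 8 did not pass (14 and 1 adjusted over the list alone), and STARD4, a sterol carrier, fell 3.05-fold, or 1.83-fold with 16 added. In the second, 12 of 28 fell, 6 rose and 10 did not pass (13 and 6 adjusted over the list alone), and the fatty acid transporter CD36 fell 8.43-fold. PLIN2, which coats lipid droplets, had a log2 difference of -2.17. Quantile normalization left 4 falls and 2 rises in the first, and 6 falls and 6 rises in the second.

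Estrogen-responsive genes split, with more falls than rises, while the receptor gene itself rose. ESR1, which encodes the target of tamoxifen, was 2.11-fold higher (log2 difference 1.08 ± 0.09, SE, adjusted p = 1.6e-30). Of 39 measured estrogen-responsive genes 24 fell, 7 rose and 8 did not pass, with 26 falls and 9 rises adjusted over the list alone. SUSD3 fell 9.97-fold and PDZK1, a scaffold protein, 5.28-fold, and TFF1 had a log2 difference of -2.31. PGR, the progesterone receptor gene, was among the rises (log2 difference 1.103), and GREB1 did not pass (0.01). The camera adjusted p was 1.5e-11, or adjusted p = 0.1 with an estimated correlation and 0.0226 under quantile normalization. Quantile normalization left 18 falls and 9 rises of this list, the fit without the trend 17 and 2, and the fit without scaling 15 and 5. Of 19 luminal epithelial genes 6 rose, 7 fell and 6 did not pass (7 and 7 adjusted over the list alone), with no shift of the list by camera (adjusted p = 0.18). Its median was -0.035 while its mean, 0.063, and camera pointed up. GATA3 (0.89), FOXA1 (0.66) and ESR1 rose and CLDN7, a tight junction claudin, fell 2.23-fold. Under quantile normalization 6 rose and 1 fell, and the median was 0.24.

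Components of the PI3K-AKT-mTOR pathway moved in both directions. Of 40 measured members 11 rose, 10 fell and 19 did not pass, with the same numbers adjusted over the list alone, and the list did not pass camera (adjusted p = 0.24). Its median was -0.012, while its mean, 0.058, and camera pointed up, and the median was 0.12 under quantile normalization. AKT1 was 1.18-fold lower (adjusted p = 0.013). However, it did not pass without the trend (adjusted p = 0.273), under quantile normalization (0.51), without scaling (0.91) or with 16 added (0.0824). With any one array left out its adjusted p was 0.0513 to 0.146. AKT2 had a log2 difference of 0.01 ± 0.09 (SE, adjusted p = 0.99), which ranged from -0.18 to 0.202 with single arrays left out. THEM4, which encodes an AKT-binding thioesterase, fell 1.69-fold (log2 difference -0.76 ± 0.11, SE). It did not pass without the trend (adjusted p = 0.0565) or without scaling (adjusted p = 0.114). PIK3CD, a catalytic subunit, was at least 2.98-fold lower, being near the lowest signal on both ELOVL2 arrays, with intensities of 13.8 and 15.8 on the control and 2.95 and 4.24 on the ELOVL2 arrays. It did not pass with its probes averaged (1.48-fold, adjusted p = 0.375), and the difference was 1.76-fold with 16 added. PIK3R1, a regulatory subunit, rose by a log2 difference of 1.101. The phosphatase genes INPP4B (0.85) and INPP5D (1.32) rose.

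Genes that FOXO transcription factors activate and AKT signalling holds down were higher as a list (camera, adjusted p = 0.00093, or adjusted p = 0.45 with an estimated correlation). Of 30 measured members 13 rose, 7 fell and 10 did not pass, also when adjusted over the list alone. The thioredoxin-binding protein gene TXNIP rose 7.57-fold, while GADD45A, a stress-response gene, fell 3.49-fold. The list median was 0.078, and fry, which asks for one direction, gave an adjusted p of 0.13. Growth factor receptor and MAPK feedback genes did not shift (camera, adjusted p = 0.46), with 7 rises, 11 falls and 13 not passing of 31, and 8 and 11 adjusted over the list alone. ETV5, a transcription factor induced by MAPK signalling, fell 5.86-fold, or 2.71-fold with 16 added.

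DNA replication genes were lower by small steps, and few mitotic genes fell. Of 35 S phase genes 30 fell, none rose and 5 did not pass, with 31 falls adjusted over the list alone and a median log2 difference of -0.51. CCNE1 (cyclin E1) fell 2.38-fold and the transcription factor gene E2F1 2.17-fold. The camera adjusted p was 1.7e-09, or adjusted p = 0.1 with an estimated correlation. Quantile normalization left 13 falls and 1 rise, with a list median of -0.369. The fit without the trend left 7 falls and the fit without scaling 5 falls. Of 35 G2 and mitosis genes 11 rose, 3 fell and 21 did not pass, also when adjusted over the list alone. For this list camera gave an adjusted p of 0.0505, or adjusted p = 0.345 with an estimated correlation. ASPM, a spindle protein gene, rose 1.72-fold. The mitotic list passed as higher in 10 of 14 other settings, among them quantile normalization (adjusted p = 1.6e-05), no trend (0.0402), no scaling (0.0488) and averaged probes (0.0166). It did not pass with median centring (0.19) or without control replicate 1, control replicate 2 or ELOVL2 replicate 1 (0.0584, 0.0654 and 0.118).

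Antioxidant and glycolytic genes were lower. Of 24 NRF2 target genes 20 fell, 2 rose and 2 did not pass, also when adjusted over the list alone (camera, adjusted p = 1.1e-09, or adjusted p = 0.1 with an estimated correlation). The aldo-keto reductase genes AKR1B10 and AKR1C1 fell, with log2 differences of -3.46 and -1.77, and their probes may not tell relatives apart. With 16 added the log2 difference of AKR1B10 was -2.25. Of 28 hypoxia and glycolysis genes 16 fell, 1 rose and 11 did not pass, with 18 and 2 adjusted over the list alone (camera, adjusted p = 1.5e-07, or adjusted p = 0.1 with an estimated correlation). ALDOC, a glycolytic aldolase, fell 5.05-fold and ADM (adrenomedullin) 3.21-fold. In the fit without the trend 12 and 13 fell. Of 28 oxidative phosphorylation genes 15 fell, none rose and 13 did not pass, with 17 falls adjusted over the list alone (camera, adjusted p = 0.00089, or adjusted p = 0.55 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, fell 2.89-fold and NDUFB8, of complex I, 1.77-fold, the latter not passing without the trend (adjusted p = 0.0612) or without scaling (0.0503). Under quantile normalization this list did not pass (adjusted p = 0.34), with 4 falls and 2 rises.

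**Figure D2:**
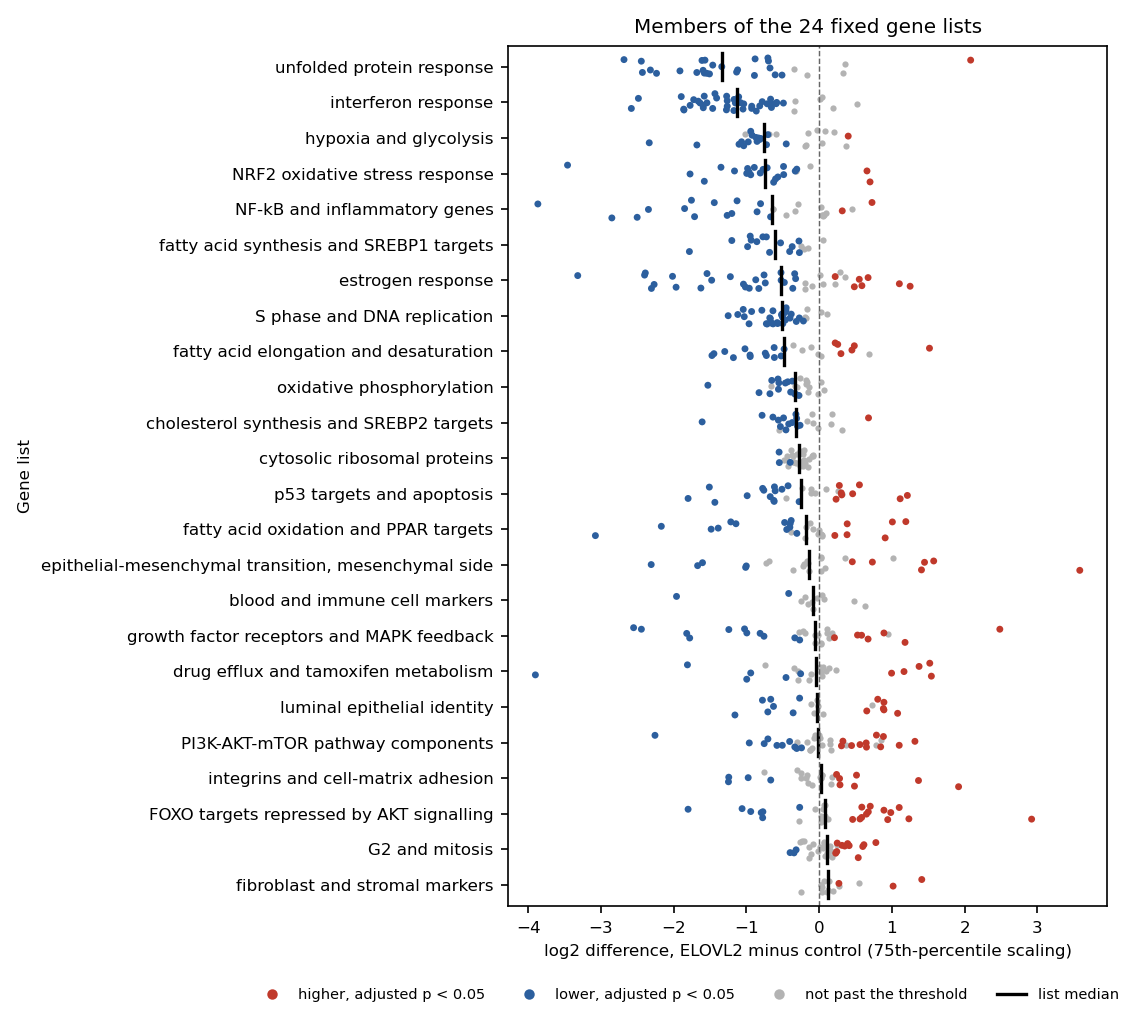
Log2 difference (ELOVL2 minus control, 75th-percentile scaling) of each measured member of the 24 fixed gene lists, with 1 point per gene, coloured where it passed the threshold, and a bar at each list's median. The medians of the unfolded protein response (-1.34) and interferon (-1.13) lists lie farthest below 0.

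The lists in this part did not pass camera in the main fit. Of 30 p53 target and apoptosis genes 14 fell, 8 rose and 8 did not pass (14 and 9 adjusted over the list alone, camera adjusted p = 0.095), led by GADD45A. This list passed as lower with median centring (adjusted p = 0.0416) and with averaged probes (0.0363), but not with an estimated correlation (0.345). Of 25 mesenchymal genes 6 rose, 5 fell and 14 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.44). Their median was -0.14 and mean 0.019, with CAV1 and VIM (1.41) among the rises and LOXL2 (-2.31) among the falls. Of 26 integrin and matrix adhesion genes 7 rose, 4 fell and 15 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.58), with a median of 0.022 and a mean of -0.027. COL4A1, a basement membrane collagen gene, was at least 2.41-fold higher, with intensities of 4.25 and 2.35 on the control arrays, both under the floor used for bounds, and 20.1 and 9.30 on the ELOVL2 arrays. The rise was 1.40-fold with 16 added, and the call was lost without the trend (adjusted p = 0.0828) and under quantile normalization (0.126). Of 24 drug efflux and tamoxifen metabolism genes 5 rose, 6 fell and 13 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.74). CYP1A1, a xenobiotic-metabolizing P450, was at least 7.16-fold lower, with intensities of 37.9 and 33.0 on the control arrays and 2.55 and 2.90, near the lowest signal, on the ELOVL2 arrays. The difference was 3.08-fold with 16 added.

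Markers of other cell types stayed mostly below the threshold. Only 4 of 15 stromal and 3 of 12 blood and immune markers lay above the median level, so not passing says little about most of them. Of the stromal markers 14 lay above 0 and 1 below, and of the blood and immune markers 4 above and 8 below. Of 15 fibroblast and stromal markers 3 rose and 12 did not pass, also when adjusted over the list alone (camera adjusted p = 0.21). The list passed as higher without the trend (adjusted p = 0.0457) and with the floor (0.046), but not with an estimated correlation (0.795). COL3A1 rose 2.66-fold from a low intensity of 4.96 and 5.55 on the control arrays, a call lost without ELOVL2 replicate 2 (adjusted p = 0.0873) and with 16 added (1.34-fold, adjusted p = 0.0685). Of 12 blood and immune markers 2 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.82), and CD14 fell 3.89-fold. Cytosolic ribosomal protein genes lay below 0 in 32 of 32 cases with a median log2 difference of -0.27, and 3 of them passed (0 adjusted over the list alone, camera adjusted p = 0.45), among them RPL19 at 1.46-fold lower, a call lost without the trend (adjusted p = 0.104), under quantile normalization (0.189) and without scaling (0.646). The list passed as lower without the trend (adjusted p = 0.000214) and with the floor (0.0343), but not with an estimated correlation (0.898). Without ELOVL2 replicate 2 camera pointed up. Under quantile normalization their median was -0.033 and none passed.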

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

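The test of the scaling between arrays and the comparison of the cultures were chosen after the results were seen, and the other tests before their result was seen. That a balanced result under quantile normalization counts for no cause was also settled afterwards.

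Probes with no gene in the annotation used here enter none of the comparisons of genes above. Of these 21389 probes, 1363 were higher with ELOVL2 and 968 were lower (limma on every probe, adjusted p under 0.05). Of the 36812 probes with a gene, 3916 were higher and 6156 lower. Whether the probes with no gene read parts of named genes is not known here.

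More genes fell than rose. The median difference was -0.059 for genes at levels of 0 to 2 and -0.304 at levels of 6 to 8. Under quantile normalization 48% of the calls were higher, and the median of the bright ribosomal protein genes was -0.033 (95% bootstrap interval -0.063 to -0.015) rather than -0.27. That normalization forces the arrays' distributions to match, which fixes both values near balance in advance, so they speak for no cause. The split depended on the scaling, and for the excess of falls the scaling, a shift of bright genes between the arrays and a true loss of abundant transcripts cannot be told apart here.

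The interferon and unfolded protein response genes were lower. Relative to genes of the same level under quantile normalization their median was -1.063 (95% bootstrap interval -1.233 to -0.816), which argues against a shift of bright genes as the whole cause. The median over the 75 genes was between -1.199 and -1.136 in the 4 pairs of an ELOVL2 and a control array, so no single array made the pattern. A difference between the cultures other than ELOVL2, such as the virus preparation or cell density, could have made it too. Arrays of different groups differed with an SD of at least 0.613 against 0.195 within a group, but each group may be 1 culture, so ELOVL2 and culture cannot be told apart.

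Of the 3 ways to split the 4 arrays into pairs, the real one called 8384 genes and the others at most 0, so that 1 split, the real one, reached that count. With 3 splits no share under 0.05 can be had.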

How the results depend on the processing

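Of the 49 named genes besides ELOVL2, 34 kept their direction and side of the threshold in every setting that included them. Most were named for a large change in the main fit, so this does not describe the calls at large. Without the trend the higher and lower counts were 882 and 1573, and the ELOVL2 log2 difference stayed at 0.711 with an adjusted p of 0.0508. Of the main calls, 846 of 3155 rises and 1547 of 5229 falls were also called there. In that fit a gene's own spread enters the test and the shared spread no longer follows the level. These 2 changes were not separated. Quantile normalization gave 2327 lower genes, no scaling 1340, a 1.5-fold minimum 1870 higher and 2794 lower, and a test of every probe 5279 higher probes. Under quantile normalization p-values rose even where a change hardly moved. IFIT3 went from -2.484 (limma, adjusted p = 3.45e-91) to -2.432 (adjusted p = 0.0112), so fewer calls there need not mean smaller changes. An unadjusted p under 0.05 was reached by 3767 higher and 5960 lower genes. Leaving out each array in turn gave 2324 to 2955 higher and 3950 to 4598 lower genes, 11 to 12 shifted lists, and an ELOVL2 log2 difference of 0.643 to 0.78. With 1 array left in a group, that array is assumed to vary like the others. AKT2, which was never called, turned to -0.105 with median centring and ranged from -0.18 to 0.202 without single arrays. The cause was not tested. ACSL6 ranged from -0.048 without ELOVL2 replicate 2 to 3.083 without ELOVL2 replicate 1. It was near the lowest signal on every array but ELOVL2 replicate 2, so its range follows from that array. Camera called 11 lists, 10 lower and 1 higher, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05 and fry called 13. Over the other settings it called 11 to 15. With the replicate number as a block, 3670 genes rose and 6039 fell, and 12 lists shifted. The labels share only a number: the differences between replicates 1 and 2 in the 2 groups correlated at 0.142 across all genes and 0.371 across genes above the median level, and with 2 pairs this does not show pairing. Without scaling, 4 fatty acid synthesis, 1 oxidative phosphorylation, 9 NRF2 and 9 hypoxia and glycolysis genes fell. The lists were not run with the robust prior. Between 45.7% and 48.7% of the probes lay near the lowest signal, where only bounds of a fold can be had.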

Other observations

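The families and gene classes in this part were chosen after the values were seen, while the tests of level and of nuclear RNA had their predictions written before their results.

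In several gene families the members that passed were mostly falls or mostly rises. S100A4, AKR1B10, AKR1C1, AKR1C3 and CAV1 are also in the fixed lists. Of 15 S100 calcium-binding protein genes 9 fell and none rose, among them S100A8 (log2 difference -3.74) and S100A9 (-3.27), whose products form calprotectin, and S100A14 (-2.90). Of 10 MHC class II genes 6 fell and none rose, with HLA-DQB1 at -2.17 and HLA-DRB1 at -1.14. Of 10 metallothionein genes 8 fell, with MT1X at -1.84, and MT1M rose. Of 16 cytosolic aminoacyl-tRNA synthetase genes 14 fell and none rose, led by WARS1 at -2.03, but 6 fell and 1 rose under quantile normalization and 2 fell without scaling. Of 9 aldo-keto reductase genes 7 fell and none rose, with AKR1B15 at -3.49. Of 7 caveolin and cavin genes 4 rose, CAV1, CAV2 (1.51), CAV3 and CAVIN1 (0.44), and none fell. CAVIN1 did not pass under quantile normalization (limma, adjusted p = 0.146). CAV3 and MT1M each had an SE of 0.463, as large as that of the dim COL4A1. They may lie near the lowest signal, so no difference is given for them. The same holds for HLA-DRB4, MAGEA8 and HLA-DPB1, counted among the falls, with SEs of 0.457, 0.456 and 0.439. Of 14 cancer-testis antigen genes of the CT45, CSAG and MAGEA families 6 fell and none rose, with CSAG1 at -3.67. Only 3 of the 7 caveolin and cavin genes, 3 of the 10 MHC class II genes and 4 of the 14 cancer-testis antigen genes lay above the median level. Without scaling 7 S100, 5 MHC class II and 6 metallothionein genes fell, and 1 metallothionein and 3 caveolin or cavin genes rose. Their paralogs can share probes.

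Beside ELOVL2, the antisense gene ELOVL2-AS1 was higher, at intensities of 187 and 142 on the ELOVL2 arrays against 45.2 and 43.5 on the control arrays, a log2 difference of 1.68 ± 0.17 (SE).

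Long non-coding genes went up more often than protein-coding genes. Above the median level, 269 of 870 rose and 197 fell, against 2118 of 10980 and 4230 for protein-coding genes. Under quantile normalization 165 rose and 77 fell, against 1707 and 1836. Compared with protein-coding genes of the same level under quantile normalization, the lncRNA median was higher by 0.13 (95% bootstrap interval 0.073 to 0.181). The interval reaches below the 0.1 set in advance, so by that limit alone level is not excluded. Without matching on level, the medians above the median level were 0.069 for lncRNAs and -0.015 for protein-coding genes under quantile normalization. Matching thus did not remove the gap, and even the interval's lower end, 0.073, had lncRNAs higher. For the lncRNAs compared, this argues against level as the whole cause, though the unmatched medians were not part of the preset test. A larger share of nuclear RNA in the ELOVL2 samples is a candidate explanation. The median of 7 nuclear-retained lncRNAs lay 0.751 above protein-coding genes of their level (interval 0.174 to 0.936). FTX was at 1.11, KCNQ1OT1 at 0.94, MALAT1 at 0.88, TUG1 at 0.75, PVT1 at 0.38 and NEAT1 at only 0.17, with MEG3 the other way at -0.39. They were not compared with other lncRNAs, which were higher too, so the values do not single out nuclear RNA. A change in the cells themselves stays open, as untested.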
